A study of Mus musculus with 132 samples.

How the data were processed

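Cortical bone of the tibia of 22 mice was segmented, pulverised and extracted by the authors, and 3′ mRNA libraries were sequenced from 6 pieces per mouse. Per the labels, cancellous bone was removed first. Per the submitters' processing notes, reads were aligned with STAR to the mouse build mm10, checked with FastQC and normalized with DESeq2. No versions are given, and neither the counting tool nor the annotation is stated. The deposited table holds a signal value per gene and library, a normalized count, for 23412 gene symbols and 132 libraries. Its header gives the mouse of each library, so the limbs and segments of a mouse could be paired. In all 132 libraries over 99% of the values were whole multiples of the smallest value above 0, within a tolerance of 0.02 of a read, so the reads behind each value could be recovered by division. Another 27 symbols in the table appear as dates and were left under those names, and 4897 genes were at 0 in every library.

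Values were taken to log2 after a pseudocount of 1 was added. Genes with a value of at least 10 in at least 4 libraries were kept, which left 13050. One limma model (limma 3.58.1 in R 4.3.3) was fitted to the 132 libraries, with a term for each combination of time, segment and limb and with the mouse as a block, and the variance followed the mean. Each loading comparison set loaded against control limbs of 1 segment at 1 time. Control limbs were compared between segments over all 22 mice. F tests asked whether the response differed between the 3 segments at a time, or between the 5 times. p values were adjusted by the Benjamini-Hochberg method within each comparison, all tests of single genes were two-sided, and the threshold was an adjusted p under 0.05. For the averages over segments, 1 difference per mouse was formed and tested with limma, a form of the test that was chosen after the data were examined. The comparisons by segment, the gene lists, the rule for named genes and the alternatives were otherwise set before the data were examined.

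Gene lists for cell types, pathways and responses were tested with camera of limma, with a preset correlation of 0.01 between genes, and again with an estimated correlation. Of these lists 36 had measured members, and the list of mitochondrially encoded genes had 0 genes in the table. In 19 comparisons, the averages over segments not among them, this made 684 tests, of which 184 passed with the preset correlation, 13 with an estimated one, and 181 without the 4 libraries that stood apart, 153 of them shared. The 5 averages made 180 more tests, of which 48 passed with the preset correlation and 1 with an estimated one. Members of a list were also counted with p adjusted over the list alone.

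Named genes were chosen by a rule. In each loading comparison it took, among genes past the threshold with the same sign in every mouse and a mean of at least 20 in the higher limb, the 5 with the highest rise and the 3 with the deepest fall. For segments it took 10 per direction with the same sign in at least 90% of mice, and for F tests the 8 smallest p. A fixed panel of bone genes and up to 4 members of each list could be named as well, passing or not. From the genes so named, those printed were picked after their values were seen, as were the list members that passed adjusted over the list alone. Numbered gene models were not named, and 1 gene that the rule takes is not reported here. Positions come from the GENCODE annotation of the same build, in which 21 of the looked-up genes overlapped another gene on the same strand.

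Beside limma, edgeR 4.0.16 was run with its quasi-likelihood test on the recovered reads, with the scaling of the authors as offset. Alternatives were a pseudocount of 0.5 or 5, no filter on low values, a filter at a mean of 50, scaling to the quantile at 75%, no mouse block, the mean log2 levels of the skeletal muscle and erythroid lists as covariates, a separate fit for each comparison, and leaving out each mouse in turn. Added after the data were examined were edgeR, a fit of each segment alone, the averages by other routes, and counts without the 4 libraries high in Msln, Upk1b, Wt1 and Krt19 or without these and 3 more libraries. The difference between shell and mid-diaphysis of each mouse was also set against the mean of the other mice by rank correlation, which was chosen after the data were examined. The labels of limbs or segments were also exchanged in up to 100 splits of the samples, the real one included. Libraries were checked for duplicates, of which there were 0, and the method was tested on simulated data with 200 changed genes.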

Results

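The series measured messenger RNA by sequencing of 3′ ends in cortical bone of the tibia of 22 female C57Bl/6J mice aged 10 weeks. The left tibia was loaded in cyclic compression at a peak of 9 N and 4 Hz for 1200 cycles per day, and the other tibia of the same mouse was the control. The cortex of each tibia was divided into 3 segments, the metaphyseal shell near the knee, the proximal diaphysis and the mid-diaphysis, which gave 6 libraries per mouse. After 1 bout of loading, 5 mice were studied at 1 h, 4 mice at 3 h and 4 mice at 24 h. Another 4 mice were loaded daily for 7 days and studied 24 h after the last bout (7d), and 5 mice were loaded for 5 days and studied on day 8 (5d). The questions of the design were which genes respond to loading at each time and whether the response differs between the segments. Levels are the deposited normalized counts, given as mean ± SD over mice. Changes are log2 differences between the loaded and control tibia of the same mouse, given ± SE, and every test of 1 gene is by limma with an adjusted p.

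The libraries held between 290325 and 5410458 reads assigned to genes, with a median of 1698310. The median was 1889380 reads in the metaphyseal shell, 1608870 in the proximal diaphysis and 1221380 in the mid-diaphysis. Between 7929 and 15110 genes had at least 1 read. Reads of a list of skeletal muscle genes made up 0.0185% to 14.6% of a library. The ribosomal RNA precursor Rn45s took 0.136% to 60.8%, with a median of 3.02% in the metaphyseal shell, 5.57% in the proximal diaphysis and 13.3% in the mid-diaphysis.

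4 mid-diaphysis libraries stood apart from the rest. They were the loaded library of mouse 2 and the control library of mouse 3 at 1 h, and the loaded libraries of mice 4 and 5 at 5d. In these libraries Msln was at 340 to 503, against at most 48.6 in the other 128, and Gata6 was at 476 to 681, against at most 18.2. The imprinted transcript H19 was at 5049 to 7173 in them and at most 1889 in the others, while Col1a1, the main chain of type I collagen, was at 4980 to 12889 against a median of 80924 over all libraries. Another 3 control libraries, mouse 3 at 3 h and mouse 2 at 7d in the proximal diaphysis and mouse 4 at 7d in the mid-diaphysis, held few genes or gave Col1a1 11.4% to 36.4% of the reads.

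**Figure D1:**
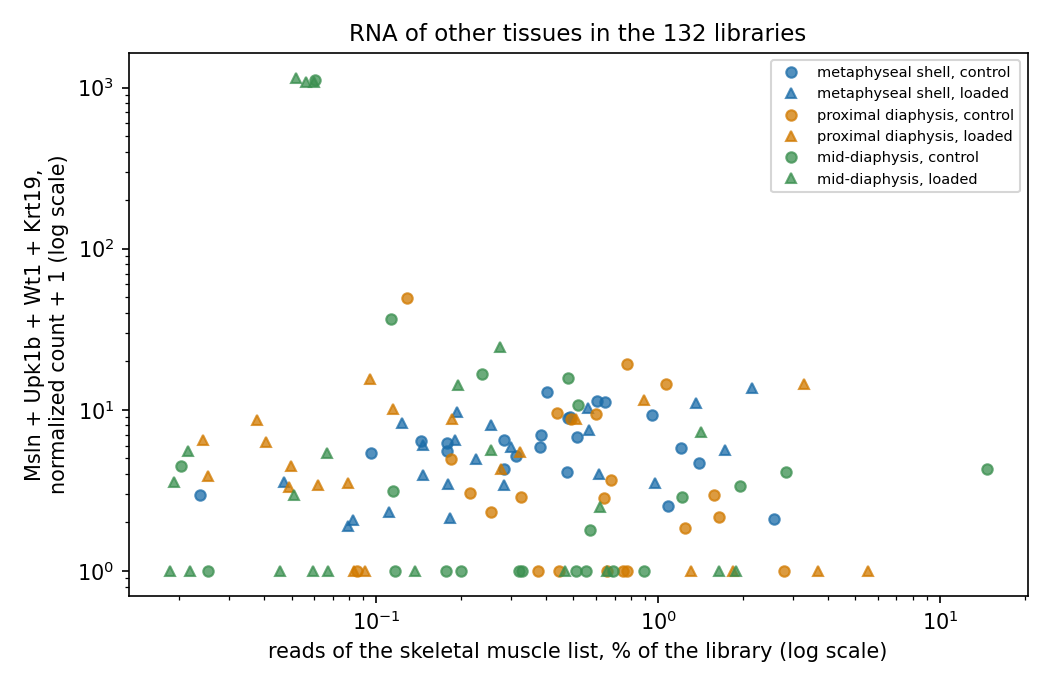
Each point is 1 library, with the share of reads from the skeletal muscle list on the horizontal log axis (%) and the summed normalized counts of Msln, Upk1b, Wt1 and Krt19, plus 1, on the vertical log axis. 4 mid-diaphysis libraries, 3 loaded and 1 control, lie far above the other 128 on the vertical axis, and muscle shares run from 0.0185% to 14.6%.

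In control tibiae the metaphyseal shell differed from the mid-diaphysis most clearly in cartilage genes. Mia, a protein secreted by chondrocytes, averaged 66.3 ± 77.4 in the shell and 4.69 ± 18.6 in the mid-diaphysis, a log2 difference of 4.40 ± 0.46 (n = 22 mice, higher in 21, adjusted p = 1.73e-11). Col10a1, the collagen of hypertrophic cartilage, was higher by 4.30 ± 0.58, and the type IX collagen genes Col9a1, Col9a2 and Col9a3 by 3.49, 3.84 and 3.63, with SE of 0.49, 0.48 and 0.50. Of the 16 measured genes of the list of chondrocyte and growth plate markers, 13 were higher over all genes tested and 14 adjusted over the list alone, and none was lower. The list as a set was higher at adjusted p = 8.67e-22 with the preset correlation, and at 0.00221 with an estimated correlation. In mouse 2 at 3 h the control segments were in the reverse order, with Mia at 0 in the shell, 8.97 in the proximal diaphysis and 87.7 in the mid-diaphysis and Col10a1 at 1.31, 38.3 and 540.3, and in its loaded tibia Col10a1 was at 0, 506 and 205. Over the genes outside the chondrocyte list, its difference between shell and mid-diaphysis in the control limb had a rank correlation of -0.249 with the mean of the other mice, against -0.0355 to 0.396 in the other 21. These libraries were kept under their labels, and without this mouse Mia was higher by 4.96 and Col10a1 by 5.04. Among the other 21 mice Col10a1 was higher in the shell than in the mid-diaphysis in 19 control and 17 loaded tibiae.

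Markers of vessels and of blood cells also distinguished these segments. Of the 16 endothelial genes, 12 were higher in the metaphyseal shell, and 14 adjusted over the list alone. Among them Eng, a receptor of the TGF-beta family on endothelium, was at 128.7 ± 66.5 against 44.8 ± 39.1, and Vwf, which encodes von Willebrand factor, was higher by 1.80 ± 0.38 (adjusted p = 7.29e-04, n = 22). The endothelial list was higher at adjusted p = 4.33e-14, and at 0.00572 with an estimated correlation. Of 14 megakaryocyte and platelet genes, 12 were higher, including Treml1 by 1.88 ± 0.28 and Gp1bb, a chain of the platelet von Willebrand receptor, by 1.65 ± 0.24. That list passed at adjusted p = 1.73e-11, and at 0.0170 with an estimated correlation. Of 16 osteoclast genes, 10 were higher over all genes and 13 adjusted over the list alone. Acp5, the tartrate-resistant acid phosphatase of osteoclasts, was at 3634 ± 1267 in the shell and 1554 ± 1254 in the mid-diaphysis (log2 1.51 ± 0.29, adjusted p = 2.07e-04, n = 22). The osteoclast list passed at adjusted p = 1.29e-08 but had an adjusted p of 0.159 with an estimated correlation. Cfd, a complement factor of fat cells, was higher by 2.64 ± 0.36 and Ramp3, a partner of the calcitonin receptor family, by 2.77 ± 0.32.

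Fewer genes were called lower than higher in the metaphyseal shell against the mid-diaphysis. Sost, which encodes the osteocyte Wnt inhibitor sclerostin, was at 123 ± 62.6 against 518 ± 381 (log2 -1.67 ± 0.34, lower in 19 of 22 mice, adjusted p = 3.86e-04). Nap1l1, a histone chaperone, was lower with a log2 difference of -0.74 ± 0.14 (n = 22, lower in 21 mice, adjusted p = 9.07e-05). The splicing genes Srsf6 and Sf3b1 had differences of -0.64 ± 0.12 and -0.40 ± 0.10. In all, 1031 of 13050 genes differed between the shell and the mid-diaphysis, 928 higher and 103 lower in the shell. edgeR called 982 genes, 675 of them shared, with 594 higher and 388 lower, and relative to limma it moved the median of all genes by -0.171. In simulated data with 2-fold changes added in the shell, limma put rises at a median log2 of 1.13 and falls at -0.81. It recovered 98% of these rises and 66% of the falls, so its split between higher and lower genes leans upward. Without 1 mouse (24 h, mouse 4) the count was 662.

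Against the proximal diaphysis, the metaphyseal shell was again higher in cartilage genes and was lower in some genes of osteocytes and the periosteum. Col10a1 averaged 220 ± 243 in the shell and 6.52 ± 9.15 in the proximal diaphysis (log2 4.39 ± 0.58, n = 22, adjusted p = 5.81e-08), and Mia and Col9a2 were higher by 3.89 ± 0.46 and 4.04 ± 0.48. Of the 16 chondrocyte and growth plate genes, 10 were higher over all genes and 13 adjusted over the list alone (adjusted p = 3.80e-21 for the list, 0.00278 with an estimated correlation). Sost was at 123 ± 62.6 in the shell and 380 ± 294 in the proximal diaphysis (log2 -1.27 ± 0.34, lower in 21 of 22 mice, adjusted p = 0.0319). Gja1, the gap junction protein connexin 43, differed by -1.02 ± 0.28, the bone-derived hormone gene Ostn by -2.18 ± 0.39, the periosteal matrix gene Postn by -1.13 ± 0.27, Aspn by -1.57 ± 0.41 and Thbs4 by -1.93 ± 0.53. With 1 of the 22 mice left out in turn, Sost stayed past the threshold in 13 cases, Gja1 in 9, Aspn in 15 and Thbs4 in 10. The osteocyte list was lower at adjusted p = 6.06e-06, with 2 of 15 genes past the threshold and 3 adjusted over the list alone. It had an adjusted p of 0.235 with an estimated correlation. Of the 20 genes for periosteum, tendon and fibroblasts 1 was lower over all genes, and adjusted over the list alone 5 were lower and 1 higher (adjusted p = 1.00e-07 for the list, 0.0854 with an estimated correlation). Cdca8, a gene of the mitotic spindle, was higher in the shell by 1.13 ± 0.22 (adjusted p = 0.00126, n = 22), and 8 of 35 cell cycle genes were higher, 13 adjusted over the list alone (adjusted p = 6.06e-06 for the list, 0.235 with an estimated correlation). Of 13050 genes, 217 differed, 181 higher and 36 lower in the shell, and edgeR called 371, 206 higher and 165 lower, 181 of them shared. The split by limma leans upward here too, since simulated 2-fold rises and falls in the shell came out at 1.075 and -0.885. Without mouse 3 of the 3 h group the count was 42, without mouse 2 of that group it was 669, and without the 4 libraries that stood apart it was 486.

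Between the 2 diaphyseal segments, genes of fibrous matrix were higher in the proximal diaphysis. Lrrc15, a membrane protein of stromal cells, averaged 100.2 ± 69.8 in the proximal diaphysis and 18.7 ± 19.1 in the mid-diaphysis (log2 2.62 ± 0.33, higher in 22 of 22 mice, adjusted p = 2.76e-08). Fmod, a small proteoglycan of tendon and periosteum, was higher by 2.43 ± 0.33, Thbs2 by 2.25 ± 0.34, Col16a1 by 1.76 ± 0.21, Col3a1 by 1.80 ± 0.33 and Dkk3 by 1.42 ± 0.26. Of 30 genes for collagens and their crosslinking, 8 were higher over all genes and 14 adjusted over the list alone, and all 30 had a positive difference (adjusted p = 5.00e-16 for the list, 0.0301 with an estimated correlation). Megakaryocyte and platelet genes were higher as a set, 5 of 14 over all genes and 11 adjusted over the list alone, with Gp1bb higher by 1.37 ± 0.24 (adjusted p = 7.03e-14 for the list, 0.0156 with an estimated correlation). Nop56, a factor of ribosome assembly, and Hnrnpd, an RNA-binding protein, were lower in the proximal diaphysis, with differences of -1.21 ± 0.25 and -0.64 ± 0.14 (adjusted p = 0.00241 and 0.00517, n = 22). Nop56 was at 0 in the proximal diaphysis of mouse 3 at 3 h and mouse 2 at 7d, 2 of the libraries with few genes, and without 7 libraries its difference was -0.62. In all 250 genes differed, 175 higher and 75 lower, and in simulated data without added changes the same comparison called 54. With upper-quartile scaling the share of higher genes moved from 70% to 80.4%, and edgeR called 304 genes, 57.6% of them higher, 190 shared. Without mouse 4 at 24 h the count was 127.

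**Figure D2:**
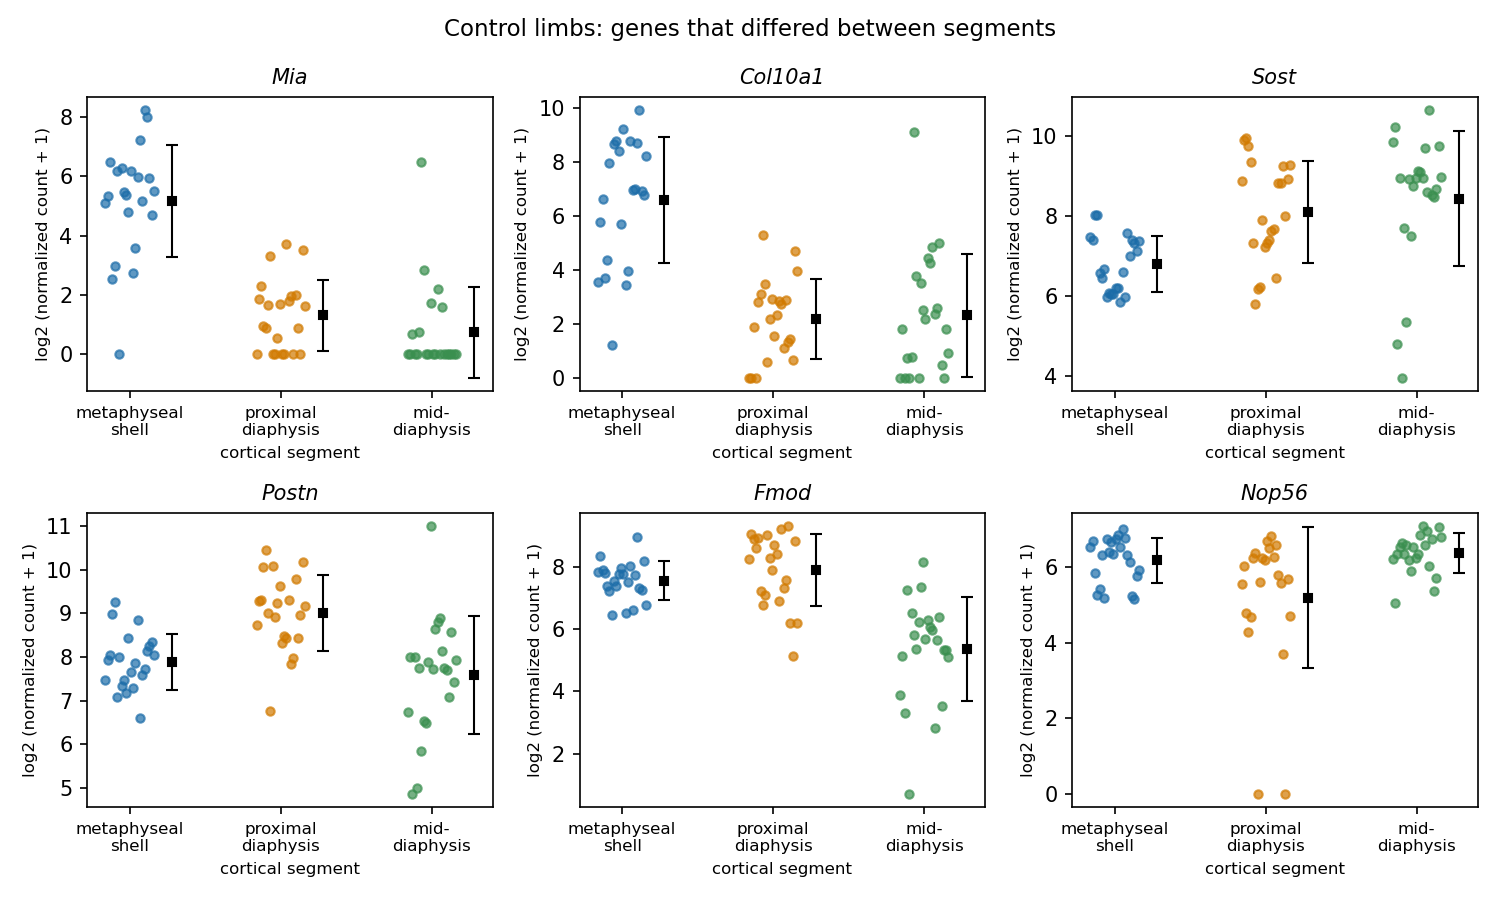
Each point is the control tibia of 1 of the 22 mice, as log2 of the normalized count plus 1, in each of the 3 cortical segments, and the squares with bars are the mean and SD. Mia and Col10a1 have their highest mean in the metaphyseal shell, and Sost and Postn lie lower there than in the proximal diaphysis.

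At 1 h after a single bout, the immediate early transcription factor genes Fosb and Egr1 rose on average over the 3 segments. Fosb went from 4.32 ± 6.75 in control to 45.7 ± 23.3 in loaded tibiae (log2 3.46 ± 0.38, n = 5 mice, adjusted p = 3.23e-06) and was higher in all 15 pairs of libraries. Egr1 went from 123 ± 84.0 to 309 ± 149 (1.46 ± 0.27, adjusted p = 0.0364, n = 5) and was higher in 13 of 15 pairs. Fosb rose in the proximal diaphysis by 3.79 ± 0.71 (adjusted p = 0.00841) and in the mid-diaphysis by 4.49 ± 0.71 (adjusted p = 1.06e-04). The call in the proximal diaphysis was lost without any of 3 of the 5 mice. Fosb in the metaphyseal shell was at 15.2 ± 9.31 against 2.39 ± 1.36, higher in 5 of 5 mice, with an adjusted p of 1. These 2 were the genes that passed in the averages over segments, by limma and by edgeR alike. Egr1 lost the threshold when any of 4 of the 5 mice was left out, with adjusted p up to 0.671.

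The list of immediate early genes rose as a set. In the average over segments 5 of its 19 measured genes rose adjusted over the list alone, which beside Fosb and Egr1 were Atf3 (1.54 ± 0.46, higher in 3 of 5 mice), Arc (1.16 ± 0.40) and Nr4a2 (0.81 ± 0.31), against 2 over all genes tested. The list passed at adjusted p = 5.52e-09, and its adjusted p was 0.0617 with an estimated correlation. In the metaphyseal shell 18 of the 19 genes had a positive difference, with a median of 0.46, and the list rose at adjusted p = 8.88e-14 and at 0.00426 with an estimated correlation, with 0 members past the threshold over all genes or adjusted over the list alone. It also passed in the proximal diaphysis and mid-diaphysis, at adjusted p = 1.01e-05 and 0.00610, and had adjusted p of 0.181 and 0.835 there with an estimated correlation. Sfrp4, a secreted Wnt antagonist, was at 24.9 ± 3.72 in loaded and 52.4 ± 31.0 in control tibiae at 1 h (-1.02 ± 0.26, lower in 5 of 5 mice). It passed adjusted over the list alone as the 1 member of 11 measured Wnt antagonists, and not over all genes (adjusted p = 0.999). The Wnt antagonist list was lower at adjusted p = 0.00221, and its adjusted p was 0.245 with an estimated correlation.

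**Figure D3:**
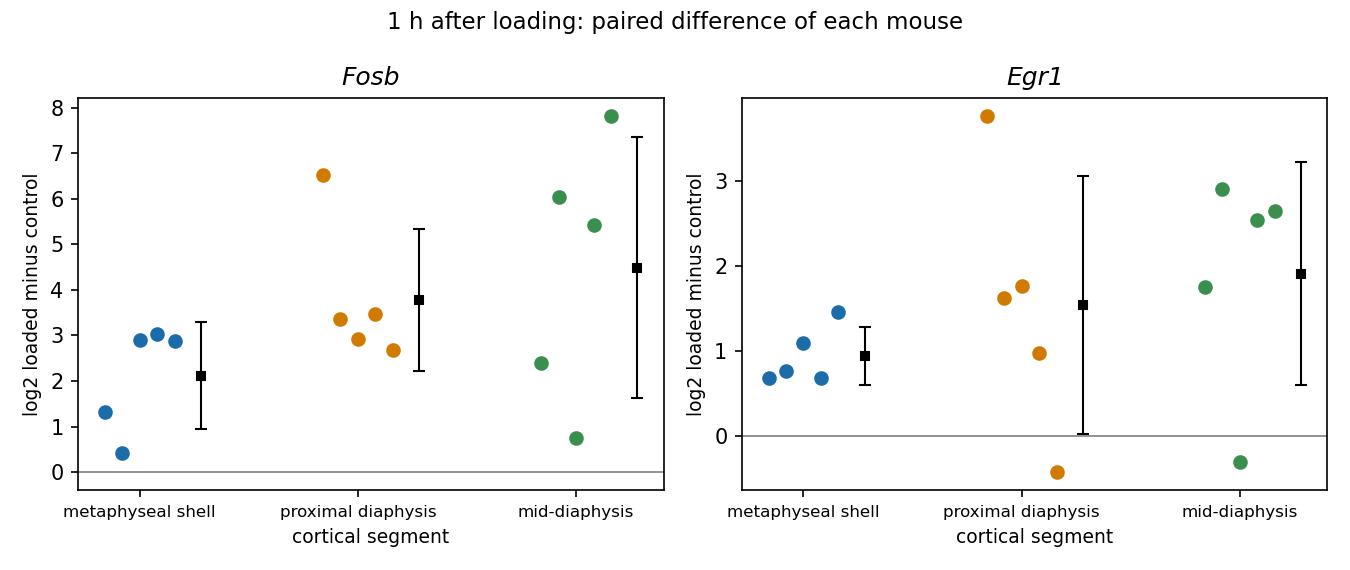
Each point is 1 of the 5 mice at 1 h, as the log2 difference of loaded minus control in each cortical segment, and the squares with bars are the mean and SD. Fosb lies above 0 in every mouse and segment, with means of 2.12, 3.79 and 4.49 from the metaphyseal shell to the mid-diaphysis.

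Counted by segment at 1 h, the mid-diaphysis had 41 changed genes, 3 up and 38 down. Nup188, a nuclear pore protein, rose from 21.6 ± 14.6 to 60.0 ± 14.9 (1.68 ± 0.42, n = 5, adjusted p = 0.0407). Pgm3, an enzyme of hexosamine synthesis, fell from 21.9 ± 12.1 to 5.04 ± 8.86 (-2.85 ± 0.57, adjusted p = 0.00742, n = 5), and the histone acetyltransferase gene Kat8 and the Wnt regulator gene Trabd2b fell by 2.97 ± 0.68 and 3.03 ± 0.71. edgeR called 65 genes, 14 of them shared. The count was 1 without mouse 1, 457 without mouse 2, whose loaded library stood apart, and 181 without the 4 libraries that stood apart, 41 of them shared. A fit of the mid-diaphysis alone, with its own spread, called 0 genes, Fosb included. limma called 0 genes in the metaphyseal shell, with 16 at an unadjusted p under 0.05, and edgeR called 0. The limma fit shares 1 spread between segments, while the median residual SD was 0.515 in the shell and 0.991 in the mid-diaphysis. In simulated data without added changes it gave 51 to 103 of 13050 genes in the shell an unadjusted p under 0.05. That share is well under 0.05, so the tests in the shell were too strict at every time. A count of 0 there does not show that no gene changed. In the proximal diaphysis Fosb was the 1 gene called by both tools.

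At 3 h the osteocyte matrix gene Dmp1 was at 534 ± 221 in loaded and 129.2 ± 33.2 in control tibiae on average over the segments (log2 1.58 ± 0.41, higher in 4 of 4 mice and in 11 of 12 pairs). It passed adjusted over the osteocyte list alone and not over all genes (adjusted p = 0.393, n = 4). Ptprz1, a receptor phosphatase, was at 122 ± 28.6 against 56.4 ± 13.4, and with Irx5 (1.04 ± 0.31) and the hyaluronan receptor gene Cd44 (0.71 ± 0.22) it made up the 4 of 15 osteocyte genes that rose adjusted over the list alone, against 0 over all genes. The osteocyte list rose at adjusted p = 0.0181, and its adjusted p was 0.716 with an estimated correlation. The growth factor gene Bmp2 was at 100.0 ± 37.7 against 51.0 ± 15.9 and Wnt7b at 15.1 ± 9.85 against 4.11 ± 1.32, neither past the threshold (adjusted p = 0.393 for both, n = 4). In the average limma called 0 genes, with 1113 at an unadjusted p under 0.05, and edgeR called 0.

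In the metaphyseal shell at 3 h, cartilage genes were lower in loaded tibiae. Col10a1 was at 46.9 ± 85.2 in loaded and 271 ± 197 in control tibiae, Col9a3 at 5.62 ± 10.8 against 61.6 ± 49.7, Hapln1 at 15.9 ± 24.8 against 87.1 ± 65.3 and Matn3 at 2.59 ± 4.86 against 26.4 ± 23.2 (n = 4 mice). The control mean of Col10a1 includes mouse 2, at 1.31 against 247 to 436 in the other 3, and without this mouse the log2 difference was -4.09 instead of -3.37. Of 16 chondrocyte and growth plate genes, 8 fell adjusted over the list alone and 0 over all genes. The list fell at adjusted p = 2.44e-31, and at 8.39e-05 with an estimated correlation. With limb labels exchanged, 5 of 35 splits, the real one included, gave a p as small. Skeletal muscle genes rose in the same comparison, and oxidative phosphorylation and ribosomal protein genes fell (unadjusted p = 2.37e-06, 6.44e-05 and 1.05e-04 by camera). In this segment limma called 0 genes in all, with 30 at an unadjusted p under 0.05, and edgeR called 0. The chondrocyte list in the shell also fell at 1 h and 24 h and rose at 7d (unadjusted p = 2.01e-06, 1.46e-11 and 1.20e-12 by camera).

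In the mid-diaphysis at 3 h, 7 genes changed, 1 up and 6 down, against 31 called in simulated data without added changes. The count was 36 without mouse 2, 2 without mouse 3 and 0 without mouse 1 or 4. Mss51, a gene of skeletal muscle mitochondria, fell from 104.9 ± 96.8 to 0.952 ± 1.15 (-5.06 ± 0.92, n = 4, adjusted p = 0.00384) and Ankrd9 fell by 3.70 ± 0.84. Arc, an immediate early gene, was at 12.3 ± 2.44 against 0.415 ± 0.651 (adjusted p = 0.0368, n = 4) and was chosen after its values were seen, since its mean lay below the level set for named genes. It lost the threshold whichever of the 4 mice was left out. The control library of mouse 4 in this segment had the highest muscle share of all libraries, 14.6%, and with the levels of the muscle and erythroid lists as covariates the count was 0. edgeR called 28 genes, 5 of them shared, and a fit of the mid-diaphysis alone called 0. In the proximal diaphysis limma called 0 genes, with 1446 at an unadjusted p under 0.05, and edgeR called 0. Without mouse 2 or mouse 1 that count was 260 or 156.

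At 24 h, Mt1, which encodes the zinc-binding protein metallothionein, fell on average over the segments from 499 ± 233 to 203 ± 74.6 (log2 -1.29 ± 0.22, n = 4 mice, lower in 12 of 12 pairs, adjusted p = 0.0274). Mmp13, a collagenase of bone, was at 404 ± 183 in loaded and 1100 ± 368 in control tibiae (-1.69 ± 0.32) and was also lower in 12 of 12 pairs, with an adjusted p of 0.0684 (n = 4). Mt1 was the 1 gene that passed with limma, edgeR called 2 genes, and Mt1 kept its call when 1 of the 4 mice was left out and lost it for each of the other 3.

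Osteoclast genes were lower as a set at 24 h. Acp5 was at 1527 ± 531 against 2696 ± 494 (-0.94 ± 0.36, lower in 12 of 12 pairs), Ctsk, the main osteoclast protease, at 439 ± 190 against 890 ± 415, and Atp6v0d2, a subunit of the osteoclast proton pump, at 57.7 ± 23.1 against 117.5 ± 39.1. In the average over segments 5 of 16 osteoclast genes fell adjusted over the list alone and 0 over all genes, and 15 of 16 had a negative difference, with a median of -0.64. The list fell at adjusted p = 3.10e-08, and its adjusted p was 0.250 with an estimated correlation. It fell in the metaphyseal shell, proximal diaphysis and mid-diaphysis at adjusted p = 1.84e-08, 7.09e-05 and 0.0117, with adjusted p of 0.376, 0.524 and 0.871 with an estimated correlation. Neutrophil and granulocyte genes were lower too, with a median of -0.27 and 17 of 18 negative (adjusted p = 0.00168 for the list, 0.631 with an estimated correlation). In the metaphyseal shell the chondrocyte and growth plate list fell as well (unadjusted p = 1.46e-11 by camera, against 1.02e-09 for the osteoclast list).

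Genes of matrix secretion were higher at 24 h. Of 26 genes of the secretory pathway and protein folding in the endoplasmic reticulum, 21 had a positive difference in the average, with a median of 0.33, including Sec24d, a coat protein of collagen-carrying vesicles, at 132.3 ± 15.4 against 79.9 ± 8.89. The list rose at adjusted p = 1.36e-05, and at 0.00957 with an estimated correlation, with 0 members past the threshold over all genes or adjusted over the list alone. In the mid-diaphysis it rose at adjusted p = 4.44e-07 and at 0.0397 with an estimated correlation, where all 25 skeletal muscle genes had a negative difference, with a median of -2.70 (adjusted p = 1.72e-14 for the list, 0.576 with an estimated correlation). Loxl2, a crosslinking enzyme of collagen, was at 606 ± 94.1 against 284 ± 92.6 (0.92 ± 0.28), and P4ha1 and P4ha2, subunits of collagen prolyl hydroxylase, were at 342 ± 26.1 against 181 ± 43.3 and 175 ± 14.2 against 88.0 ± 18.7. These 3 of 30 genes for collagens and their crosslinking rose adjusted over the list alone and 0 over all genes (adjusted p = 0.00805 for the list, 0.631 with an estimated correlation). Cthrc1, a secreted protein of osteoblasts, was at 230 ± 40.1 against 66.1 ± 35.2 and was the 1 of 22 osteoblast and bone matrix genes that rose adjusted over the list alone (adjusted p = 0.00529 for the list, 0.720 with an estimated correlation).

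The Wnt ligand genes were lower in the proximal diaphysis at 24 h. Wnt7b was at 0.890 ± 1.31 in loaded and 10.4 ± 9.47 in control tibiae there, lower in 4 of 4 mice, and was the 1 of 11 measured ligand genes that fell adjusted over the list alone. The list fell at adjusted p = 5.27e-04, and at 0.0404 with an estimated correlation. Lists of marrow and blood cells fell in the same comparison, neutrophils at adjusted p = 2.11e-04, monocytes at 5.27e-04, marrow stroma at 0.00123, B lymphocytes at 0.00371 and erythroid cells at 0.0347, with adjusted p of 0.683, 0.541, 0.318, 0.532 and 0.840 with an estimated correlation. On average over the segments Wnt7b was at 2.36 ± 1.58 against 8.86 ± 2.26 (-1.81 ± 0.48, adjusted p = 0.945, n = 4).

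By segment at 24 h, limma called 0 genes in the metaphyseal shell and 0 in the proximal diaphysis, with 40 and 171 at an unadjusted p under 0.05, and edgeR called 0 in both. In the mid-diaphysis 1 gene rose, Ephx4, an epoxide hydrolase, at 20.6 ± 11.999 against 0.591 ± 1.18 (adjusted p = 0.0159, n = 4). By the size of its control SD, a single control library was above 0 for Ephx4. edgeR called 0 there, a fit of the mid-diaphysis alone called 0, and Ephx4 lost the threshold without any of 3 of the 4 mice.

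After 5 days of loading, on day 8, Mt1 rose on average over the segments from 233 ± 21.7 to 501 ± 112.8 (log2 1.09 ± 0.20, n = 5 mice, higher in 13 of 15 pairs, adjusted p = 0.0215). 4 genes fell. They were Cdo1, an enzyme of cysteine breakdown, from 191 ± 38.2 to 97.4 ± 20.9 (-1.25 ± 0.23, lower in 15 of 15 pairs, adjusted p = 0.0215), the axon guidance gene Sema3d (-1.57 ± 0.28, adjusted p = 0.0215), Pgbd5, which derives from a transposase (-1.96 ± 0.37, adjusted p = 0.0254), and the fast myosin gene Myh2 (-3.57 ± 0.71, adjusted p = 0.0476). Pgbd5 was chosen after its values were seen, since its mean lay below the level set for named genes. edgeR called 18 genes, 4 of them shared, and without the 4 libraries that stood apart the count was 1. It was 0 without mouse 1, 4 or 5, 3 without mouse 3 and 9 without mouse 2, and Mt1 lost the threshold whichever of the 5 mice was left out, with adjusted p up to 0.397, and without the 4 libraries. With the levels of the muscle and erythroid lists as covariates it was 0.

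Genes of osteoblasts and bone matrix were lower at 5d. Of 22 genes, 14 fell adjusted over the list alone and 0 over all genes. Among them Ifitm5 was at 92.4 ± 43.7 in loaded and 189 ± 52.2 in control tibiae (-1.18 ± 0.29), Phospho1, a phosphatase of mineralisation, at 35.3 ± 21.1 against 64.1 ± 29.7, Cthrc1 at 25.9 ± 5.34 against 62.2 ± 34.8, and Col1a1 at 32506 ± 13974 against 59725 ± 20700 (n = 5). The loaded means include the 2 mid-diaphysis libraries that stood apart, in which Col1a1 was low. In single mice Col1a1 differed by -0.855 to -0.0348 in the shell and -2.02 to 0.225 in the proximal diaphysis. In the mid-diaphysis it differed by -3.63 to 0.723, with 2 of 5 mice above 0. The list fell at adjusted p = 7.02e-18, and its adjusted p was 0.300 with an estimated correlation. Without the 4 libraries that stood apart it fell at adjusted p = 5.87e-12. Of 30 genes for collagens and their crosslinking, 11 fell adjusted over the list alone, including Loxl2 at 94.2 ± 68.5 against 228 ± 203 (adjusted p = 3.26e-06 for the list, 0.300 with an estimated correlation). Skeletal muscle genes fell in the same average, 18 of 25 adjusted over the list alone and 1 over all genes, with a median of -2.03 (adjusted p = 4.61e-13 for the list, 0.461 with an estimated correlation). In the proximal diaphysis the muscle list fell at adjusted p = 1.45e-40 and at 0.0419 with an estimated correlation, with Myh2 at 31.4 ± 56.3 against 211 ± 142 and the myoglobin gene Mb at 46.7 ± 73.9 against 302 ± 169. Lists that rose there included cell cycle, marrow stroma, monocyte, osteoclast and erythroid genes (unadjusted p = 1.89e-07, 5.13e-04, 6.225e-04, 0.00117 and 0.001715 by camera). With limb labels exchanged, 37, 3 and 18 of 100 splits, the real one included, gave a muscle list p as small, from the shell to the mid-diaphysis.

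In the metaphyseal shell at 5d, genes of periosteum and tendon rose as a set. Tnmd, a tendon membrane protein, was at 64.8 ± 72.2 in loaded and 3.76 ± 1.48 in control tibiae, Thbs4 at 97.6 ± 118.1 against 7.09 ± 5.30 and Dpt at 23.8 ± 20.6 against 3.81 ± 2.83. Of the 20 genes for periosteum, tendon and fibroblasts 17 had a positive difference (adjusted p = 4.99e-14 for the list, 0.00528 with an estimated correlation), with 0 past the threshold over all genes or adjusted over the list alone. The 1 gene called in this segment was Kera, a small proteoglycan of cornea and tendon, at 19.5 ± 18.96 against 0.122 ± 0.274 (adjusted p = 0.00781, n = 5). It was chosen after its values were seen, it lost the threshold without any of 3 of the 5 mice, and edgeR called 0. By the size of the control SD of Kera, a single control library was above 0. In the proximal diaphysis limma called 0 genes, with 322 at an unadjusted p under 0.05, and edgeR called 0.

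In the mid-diaphysis at 5d, 385 genes changed, 230 up and 155 down, in the segment where 2 of the 5 loaded libraries were among the 4 that stood apart. The small GTPase gene Rras rose from 7.69 ± 5.44 to 101.01 ± 68.0 (3.42 ± 0.55, n = 5, adjusted p = 1.06e-04), the fatty acid elongase gene Elovl6 by 3.79 ± 0.73, the adhesion gene Pvrl2 by 3.63 ± 0.67, the tubulin gene Tubb2b by 3.91 ± 0.85 and the lipid phosphatase gene Ppap2c by 3.45 ± 0.73. Dlx3, a transcription factor of osteoblasts, fell from 64.4 ± 41.6 to 13.9 ± 17.9 (-3.24 ± 0.79, adjusted p = 0.0193, n = 5), Txlnb fell by 3.81 ± 1.06 and Churc1 by 3.20 ± 0.79. edgeR called 363 genes, 317 up and 46 down, 150 of them shared. Without the 4 libraries the count was 7, 1 up and 6 down, 2 of them shared, and it was 9 without mouse 5, 43 without mouse 4, 1167 without mouse 2, 596 without mouse 1 and 0 in a fit of the segment alone.

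After 7 days of loading, 16 genes changed on average over the segments, 14 up and 2 down. Zscan12, a zinc finger gene, rose from 7.18 ± 3.47 to 30.4 ± 15.1 (log2 2.30 ± 0.36, n = 4 mice, higher in 11 of 12 pairs, adjusted p = 0.00495). The phosphoinositide phosphatase gene Mtmr14 rose by 1.86 ± 0.34, the proteasome chaperone gene Psmd10 by 1.81 ± 0.31 and the centriole gene Poc1b by 1.64 ± 0.32. Lepre1, which encodes a collagen prolyl hydroxylase, fell from 280 ± 94.1 to 150 ± 32.0 (-0.96 ± 0.21, adjusted p = 0.0446, n = 4) and Tmem45a fell by 1.44 ± 0.30 (adjusted p = 0.0434). edgeR called 137 genes, 7 of them shared, and the count ran from 1 to 243 when 1 mouse was left out. With the levels of the muscle and erythroid lists as covariates it was 0, and without 7 libraries it was 6, 2 of them shared. Upper-quartile scaling moved the share of genes that rose from 87.5% to 100%.

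Bone matrix genes were lower at 7d. Of 22 osteoblast and bone matrix genes, 8 fell adjusted over the list alone and 0 over all genes, among them Col1a1, at 126610 ± 33783 in loaded and 278820 ± 117100 in control tibiae (-1.19 ± 0.36), Cthrc1 at 94.1 ± 43.1 against 161 ± 28.3, and Tnn, a tenascin of periosteum, at 156 ± 111.2 against 210.5 ± 108.3, with a difference of -1.99 ± 0.45 (adjusted p = 0.0563, n = 4) that was -5.25 in the mid-diaphysis and 0.48 in the metaphyseal shell. The list fell at adjusted p = 4.38e-11, and its adjusted p was 0.348 with an estimated correlation. With limb labels exchanged, 9, 7 and 8 of 35 splits, the real one included, gave a p as small from the shell to the mid-diaphysis. In single mice Col1a1 differed by -0.749 to 0.671 in the shell, -3.355 to -0.571 in the proximal diaphysis and -4.60 to -0.238 in the mid-diaphysis. The control libraries of mouse 2 in the proximal diaphysis and mouse 4 in the mid-diaphysis were among those set apart for few genes or a large Col1a1 share. Of 30 genes for collagens and their crosslinking, 7 fell and 1 rose adjusted over the list alone. P4ha2 was at 58.8 ± 19.2 against 123 ± 49.5, Loxl2 at 357 ± 123 against 634 ± 96.01 and Col5a2 at 2737 ± 683 against 4925 ± 1378 (adjusted p = 1.51e-09 for the list, 0.192 with an estimated correlation). Of 25 skeletal muscle genes, 22 fell adjusted over the list alone, and Mb was at 65.9 ± 102 against 218 ± 198 (adjusted p = 2.26e-13 for the list, 0.424 with an estimated correlation). The muscle list fell in the metaphyseal shell at adjusted p = 3.99e-51 and at 0.0105 with an estimated correlation, with Myh2 at 9.83 ± 14.9 against 214 ± 224.

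In the proximal diaphysis at 7d, 205 genes changed, 194 up and 11 down. Mtmr14 rose from 7.94 ± 9.44 to 40.2 ± 7.13 (3.32 ± 0.68, n = 4, adjusted p = 0.0119), the lymphocyte gene Gimap3 by 3.44 ± 0.83, Taf1c by 3.30 ± 0.83 and Ncald by 3.17 ± 0.76, and the lectin gene Cd209d was at 20.4 ± 25.1 against 0.473 ± 0.624. Pgbd5 fell from 45.6 ± 9.66 to 8.69 ± 7.26 (-2.69 ± 0.61, adjusted p = 0.0152, n = 4), and Fkbp11, a folding factor of secreted proteins, and the phosphodiesterase gene Smpdl3b fell by 2.36 ± 0.53 and 2.77 ± 0.77. edgeR called 126 genes, 56 of them shared and 54.8% of them up. Without mouse 2, whose control library held few genes, the count was 0, without mouse 4 it was 1070, without mouse 3 it was 817, without mouse 1 it was 374, and a fit of the segment alone called 0.

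In the mid-diaphysis at 7d, 350 genes changed, 204 up and 146 down. The deacetylase gene Hdac6 was at 24.7 ± 10.2 in loaded and 0.807 ± 1.61 in control tibiae (adjusted p = 1.00e-04, n = 4). Dnajb12, Rassf7 and Mtbp were at 33.8 ± 27.4, 24.2 ± 8.54 and 22.7 ± 14.5 in loaded against 1.88 ± 3.77, 1.44 ± 2.89 and 0.289 ± 0.578 in control tibiae. For these genes and Hdac6 the control SD was 2 times the mean, which with n = 4 occurs only where a single control library is above 0. Their rises thus start from values at the floor. Tnn fell from 113.3 ± 76.5 to 4.58 ± 8.16 (-5.25 ± 0.90, adjusted p = 1.92e-04, n = 4), the endothelial claudin-like gene Tmem204 fell by 4.02 ± 0.65, and Dagla, an enzyme of endocannabinoid synthesis, was listed at 0 in all 4 loaded libraries and at 24.7 ± 30.2 in control tibiae. edgeR called 652 genes, 238 of them shared. The count was 199 without mouse 4, with 71 of them up, 456 without 7 libraries, with 42.1% of them up, 661 without mouse 2 and 0 in a fit of the segment alone. limma called 0 genes in the metaphyseal shell, with 1.1e+02 at an unadjusted p under 0.05, and edgeR called 0.

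In the fit over all libraries the response of 17 genes differed between the 5 times, and edgeR called 37. The count was 6 with 1 difference per mouse, 7 without the mouse block, 8 among genes with a mean of at least 50, and 4 without mouse 1 or 2 of 24 h. The differences that follow are averages over segments, with SE at each time from 1 difference per mouse. Their adjusted p, and the SE of the difference between 7d and 5d, come from the fit over all libraries. That fit counts the 3 segments of a limb as separate measurements, so these p may be too small. Which of the named genes are among the 6 is not given here. Mt1 had differences of -0.07 ± 0.20 at 1 h, 0.06 ± 0.22 at 3 h, -1.29 ± 0.22 at 24 h, 1.09 ± 0.20 at 5d and 0.24 ± 0.22 at 7d (adjusted p = 2.76e-05). Egr1 was at 1.46 at 1 h and 0.81 at 3 h, and at -0.53, 0.54 and -0.73 at 24 h, 5d and 7d (adjusted p = 0.0196). Fkbp11 was at 1.09 ± 0.30 at 24 h and -1.22 ± 0.30 at 7d (adjusted p = 0.0261), and Sema3d at 1.04 ± 0.31 at 3 h and -1.57 ± 0.28 at 5d (adjusted p = 0.0278). Aldh1l2, a mitochondrial enzyme of folate metabolism, was at 1.31 ± 0.39 at 3 h and -0.92 ± 0.35 at 5d (adjusted p = 0.0283). Psmd10 and Zscan12 had their highest differences at 7d (adjusted p = 0.0202 and 0.00163). Zscan12 was the 1 gene whose response differed between 7d and 5d, by 2.98 ± 0.50 (adjusted p = 4.64e-04), with 2.30 at 7d and -0.68 at 5d, and edgeR called 1 gene. Sost passed at no time, with averages of -0.14 ± 0.35, 0.23 ± 0.39, -0.40 ± 0.39, -0.12 ± 0.35 and 0.08 ± 0.39 from 1 h to 7d.

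The response was tested for a difference between the segments at each time. limma called 0 genes at 1, 3 and 24 h, with 576, 514 and 168 at an unadjusted p under 0.05, and edgeR called 5, 1 and 0. At 5d it called 3, which were Rras, Ninj1, a cell adhesion gene, and Fbxo2, with an adjusted p of 0.0335 for each. Rras and Ninj1 had differences of 3.42 ± 0.55 and 3.17 ± 0.52 in the mid-diaphysis, and Fbxo2 was chosen after its values were seen. At 7d it called 32. Tmem204 was at -4.02 ± 0.65 in the mid-diaphysis, 1.85 ± 0.65 in the proximal diaphysis and 0.16 ± 0.65 in the metaphyseal shell (adjusted p = 2.22e-04, n = 4), and Sap18 was at 2.75 ± 0.61 in the mid-diaphysis and -1.68 ± 0.61 in the proximal diaphysis (adjusted p = 0.0213, n = 4). Without the 4 libraries that stood apart the counts were 21 at 1 h, 0 at 5d and 67 at 7d. Separate fits and a mean of at least 50 each gave 0 at 5d and 0 at 7d, where edgeR called 5 and 164. In simulated data with changes in the shell at 1 h, this test by limma recovered 4% of 2-fold and 46% of 4-fold rises. Of falls it recovered 2% and 36%, so the counts of 0 do not show that the segments responded alike.

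**Figure D4:**
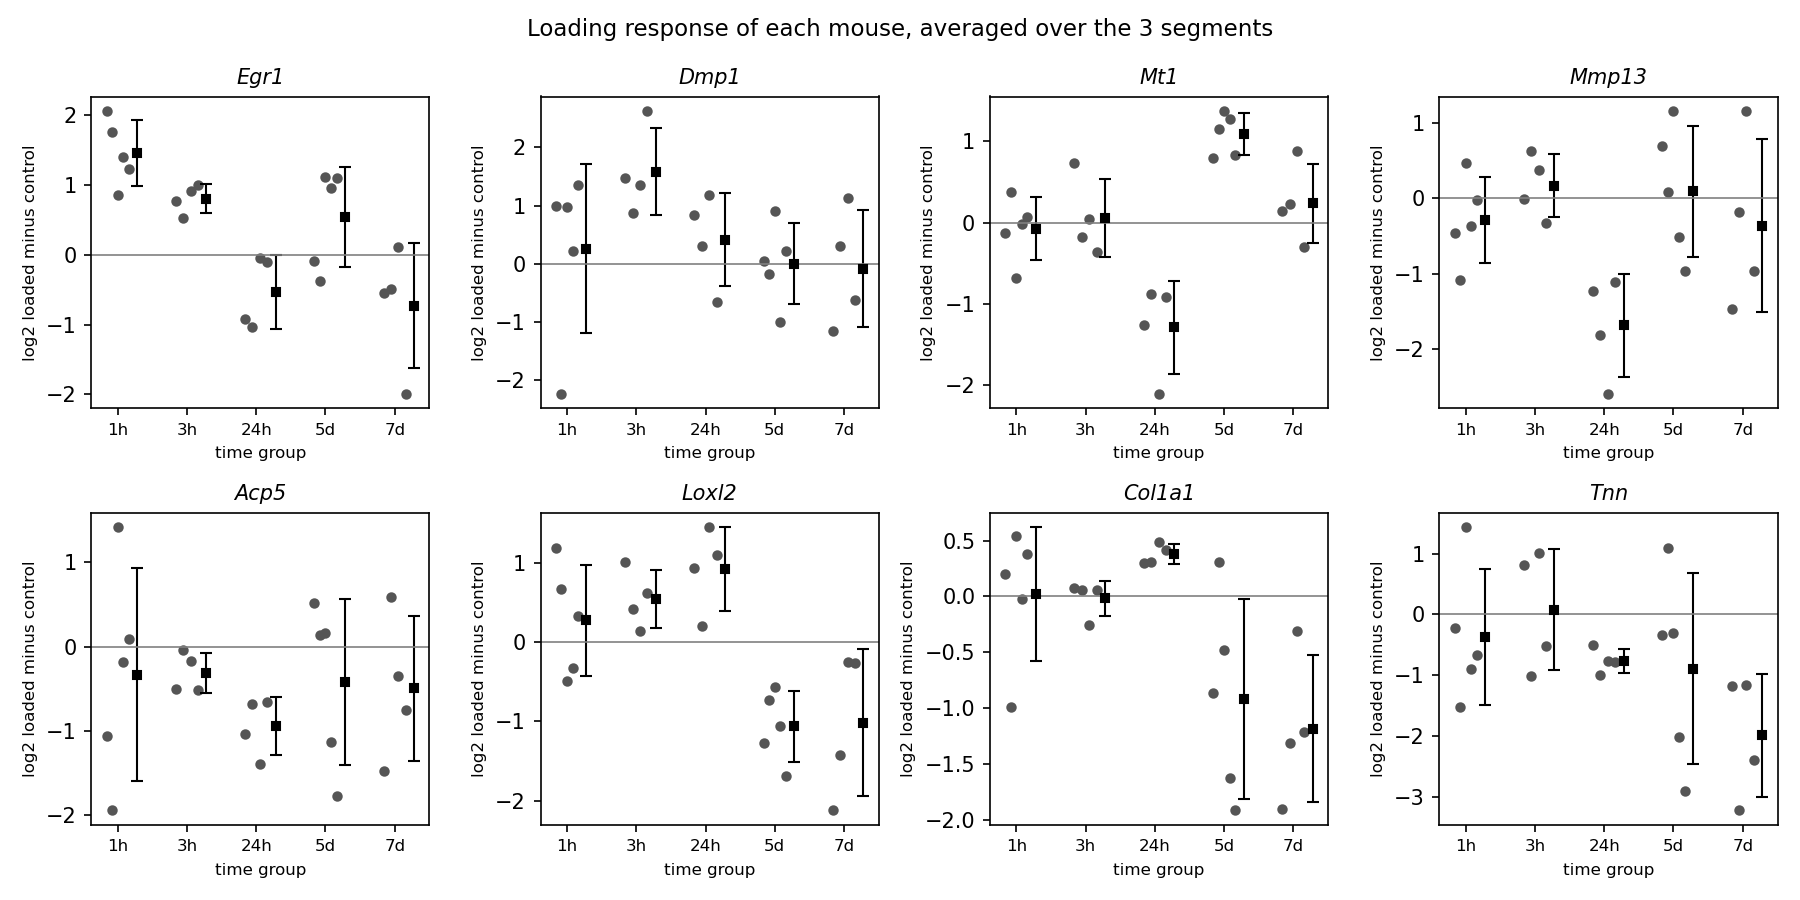
Each point is 1 mouse, as the log2 difference of loaded minus control averaged over the 3 segments, at each of the 5 times, for 8 genes, and the squares with bars are the mean and SD. Mt1 lies at -1.29 at 24 h and 1.09 at 5d, and Col1a1 lies at -0.92 at 5d and -1.19 at 7d.

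The method was tried on counts simulated gene by gene from the control means and spread of each segment, without mouse effects. Among changes put into these counts, rises of 2-fold in the metaphyseal shell at 1 h were recovered in 8% of genes. Those of 4-fold were recovered in 76%, and a fit of the shell alone recovered 50% and 98%. In the average over segments at 24 h the shares were 34% and 98%. Of the named genes with known positions, Fosb lies on chromosome 7 from 19302696 to 19310051, Egr1 on chromosome 18 from 34859823 to 34864984, Mt1 on chromosome 8 from 94179082 to 94180327, Mmp13 on chromosome 9 from 7272514 to 7283331 and Dmp1 on chromosome 5 from 104202613 to 104214102, in the mouse build mm10.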

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

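The tests of the counts at 7d, of osteoclast against marrow genes and of samples that lay apart were chosen after the results were seen, and the 2 tests of the mid-diaphysis at 5d before.

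The 385 genes called in the mid-diaphysis at 5d may reflect RNA of other cells in 2 of the 5 loaded libraries, those of mice 4 and 5, which were high in Msln, Upk1b, Wt1 and Krt19. Of the called genes 93.5% had the same sign in the 2 libraries of 1 h that were high in the same markers, against 67.4% of the genes not called and 36.1% to 58.7% in other pairs of 1 h libraries. Without the loaded libraries of mice 4 and 5 the count was 0. Pairs of mouse 3 with mouse 4 or 5 also gave 0, which was the outcome first set against this explanation, and the comparison was then limited to pairs with neither mouse (1381 to 2718 genes), because a pair with 1 of them loses part of the same signal (0 to 316 genes). Of the 2 libraries of 1 h, 1 was from the control limb of mouse 3, so the markers were high in a library labelled as not loaded. Foreign cells, exchanged samples and a response to loading in mice 4 and 5 at 5d stay open, and no cell type was tested as the source.

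The counts at 7d, 350 genes in the mid-diaphysis and 205 in the proximal diaphysis, could come from the larger spread between libraries there or from 1 control library with few genes. The median residual SD was 0.991 in the mid-diaphysis and 0.786 in the proximal diaphysis, against 0.515 in the metaphyseal shell, and a fit of each segment alone called 0 genes in the mid-diaphysis and 0 in the proximal diaphysis. In simulated data without added changes the shared fit called 26, 31 and 104 genes in the mid-diaphysis at 1 h, 3 h and 5d. The fit of that segment alone called 1, 0 and 0. In the proximal diaphysis at 7d the shared fit called 7 in simulated data, against 205 in the real data. The simulated counts hold no mouse effects or links between genes, while splits of the real samples there gave up to 718 genes. The 7 therefore cannot decide whether spread gave the 205. With 200 changes added to simulated data in the mid-diaphysis at 7d, 45 of the genes that the shared fit called, 38.5%, were false. Without the 1 control library with few genes or a large Col1a1 share, 167 genes were called in the mid-diaphysis and 0 in the proximal diaphysis, but without 7 libraries, this one among them, the mid-diaphysis had 456, 208 of them shared with the 350. A response to loading stays open, since the fit of the mid-diaphysis alone recovered 10% of simulated 4-fold rises at 7d.

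The lower level of osteoclast genes at 24 h could come from a lower share of marrow cells in the loaded limb, which would lower the erythroid, neutrophil, B lymphocyte and monocyte lists alike. In the proximal diaphysis the osteoclast genes lay -0.19 ± 0.66 (SD, n = 4 mice) from the marrow lists, which were themselves at -0.50 and lower in 4 of 4 mice, so a lower share of marrow stays possible there. In the metaphyseal shell the difference was -0.52 ± 0.58, lower in 4 of 4 mice, with the marrow lists at -0.11 ± 0.20, and in the mid-diaphysis it was -0.38 ± 0.28, lower in 3 of 4 mice, with the marrow lists at -0.28 ± 0.09 and lower in 4 of 4. In all 3 segments the spread between 4 mice keeps it open whether marrow or osteoclasts changed. The condition that the marrow lists fall by more than 1 SD in all mice was added after the first outcome was seen, because a share that did not fall cannot lower other genes, and it changed the outcome for the metaphyseal shell.

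Of 224 groups of 4 or 5 samples, 22 held 1 sample far from the others by Dixon's test, which flags about 1 in 20 groups by chance if values are normally distributed. Muscle shares, which are skewed, were tested without taking logs, so the 22 cannot be set against that rate. Among log2 differences these were, with the range of the other mice, Fosb in the proximal diaphysis at 1 h (6.52 in mouse 1, others 2.69 to 3.47), Txlnb in the mid-diaphysis at 5d (-5.95 in mouse 5, others -3.48 to -2.97), Smpdl3b in the proximal diaphysis at 7d (-6.20 in mouse 2, others -2.10 to -1.37), Mtbp in the mid-diaphysis at 7d (0.73 in mouse 1, others 4.63 to 5.25) and Rspo1 in the proximal diaphysis at 24 h (-1.30 in mouse 2, others -1.94 to -1.87). In the averages they were Wnt7b at 3 h (-0.50 in mouse 2, others 2.33 to 2.74) and Sost at 24 h (0.17 in mouse 2, others -0.61 to -0.58).

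Among libraries, reads were 806996 in the loaded proximal diaphysis of mouse 4 at 3 h (others 1856600 to 2047240) and 3674974 in the control metaphyseal shell of mouse 1 at 5d (others 1534240 to 2086650), and 9748 genes were detected in the loaded mid-diaphysis of mouse 3 at 5d (others 12472 to 12835). The summed level of Msln, Upk1b, Wt1 and Krt19, tested on the log2 scale, was 1150 in the loaded mid-diaphysis of mouse 2 at 1 h (others 0 to 1.51), 1.32 in the loaded metaphyseal shell of mouse 2 at 3 h (others 7.04 to 9.23) and 0 in the control mid-diaphysis of mouse 1 at 3 h (others 3.10 to 3.50). The muscle share was high in 8 loaded libraries and 1 control library. In the loaded proximal diaphysis it was 3.28% in mouse 3 at 1 h (others 0.0376% to 0.510%), 3.70% in mouse 3 at 24 h (others 0.0243% to 0.0951%), 0.894% in mouse 1 at 5d (others 0.0407% to 0.115%) and 5.55% in mouse 4 at 7d (others 0.0252% to 0.0835%). In the loaded mid-diaphysis it was 0.255% in mouse 3 at 3 h (others 0.0454% to 0.0669%), 1.41% in mouse 4 at 24 h (others 0.0214% to 0.0675%) and 0.276% in mouse 4 at 7d (others 0.0185% to 0.0594%), and in the loaded metaphyseal shell 0.973% in mouse 3 at 24 h (others 0.179% to 0.193%). In the control proximal diaphysis it was 2.81% in mouse 3 at 7d (others 0.128% to 0.444%).

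Named genes whose response differed between groups by an F test were, between segments at 5d, Ninj1 and Rras (adjusted p = 0.0335 for both), and at 7d Tmem204 (2.22e-04), Coq7, Sap18, Akip1, Fnip2 and Arl2 (0.0213 for each) and Wash and Vrk3 (0.0222 for both). Between the 5 times they were Mt1 (2.76e-05), Zscan12 (0.00163), Egr1 (0.0196), Psmd10 (0.0202), Fkbp11 (0.0261), Sema3d (0.0278) and Aldh1l2 (0.0283). Zscan12 also differed between 7d and 5d (4.64e-04). All of these adjusted p come from the fit over all libraries.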

How the results depend on the processing

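The averages over segments, edgeR, the fit of each segment alone, the averages by other routes, and the counts without 4 or 7 libraries were chosen only after the results were seen. All 86 tests of named genes that passed kept their direction under every alternative run for them, and 1636 of the 1961 repeats under alternatives still passed. The rule for loading and segment comparisons took genes with the same sign in every mouse, or in at least 90% of mice for segments. That choice favours a kept direction, so the kept direction is weak support. Counts are given for the metaphyseal shell (MS), proximal diaphysis (PD), mid-diaphysis (MD) and the average over segments, and those not listed stayed within 1.5 times the main count. The cause of a change was not tested unless the alternative itself shows it, as where genes or libraries were removed. The depth, 290325 to 5410458 reads, limits tests of genes with few reads. DESeq2 was not run, and the test of counts was that of edgeR on the recovered reads.

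Without the mouse block, the contrast of MS with PD called 1.1e+02 genes instead of 217, the averages 1 at 1 h, 0 at 24 h and 26 at 7d, the F tests between segments 0 at 5d and 20 at 7d, and that between the 5 times 7. For deviations from the mean of each group of libraries, the mean correlation was 0.0574 within mice and -0.0585 between mice of a time. Removing the group means itself pushes the second value below 0, so it is no measure of how far mice differ. Within mice the mean was over 0.1 in 4 of 22. The other counts stayed within 1.5 times.

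A pseudocount of 0.5 gave 0 genes in PD at 1 h, 3 in MD at 3 h, 0 in MD at 24 h, 1 in the average at 1 h, 39 in that at 7d, and 1 between segments at 1 h. A pseudocount of 5 gave 3 in MD at 1 h, 11 in MD at 3 h, 2 in MS at 7d, 58 in PD at 7d, 5 in the average at 7d, and 2, 1 and 0 between segments at 3 h, 24 h and 5d. No filter on low values gave 9 in MS and 5 in PD at 1 h; 4, 2 and 48 in MS, PD and MD at 3 h; 9, 3 and 81 at 24 h; 11, 7 and 596 at 5d; 20 in MS at 7d. It gave 1, 0 and 0 in the averages at 1 h, 24 h and 5d, and 6, 1 and 8 between segments at 3 h, 24 h and 5d. A mean of at least 50, with fewer genes tested, gave 0 in PD and 0 in MD at 1 h, 32 in PD and 0 in MD at 3 h, 0 in MD at 24 h, 0 in MS and 173 in MD at 5d, and 1.1e+02 in MD at 7d. It gave 466 for MS against MD, 149 for PD against MD, 0 between 7d and 5d, 0, 3 and 5 in the averages at 1 h, 5d and 7d, 0 between segments at 5d and 0 at 7d, and 8 between the 5 times.

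With upper-quartile scaling every count stayed within 1.5 times. The levels of the muscle and erythroid lists as covariates gave 62 in MD at 1 h, 0 in MD at 3 h, 5 in MD at 5d, 0 in the averages at 5d and at 7d, and 1, 0 and 67 between segments at 1 h, 5d and 7d. Separate fits, with fewer libraries each, gave 0 in PD and MD at 1 h, 1 in MD at 3 h, 0 in MD at 24 h, 0 in MS and MD at 5d, 0 in PD and MD at 7d, 141 for MS against PD, 0 between 7d and 5d, and 1, 0 and 0 between segments at 24 h, 5d and 7d.

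Without the 4 libraries high in Msln the counts were 181 in MD at 1 h, 2 in MD at 24 h, 7 in MD at 5d, 360 in PD at 7d, 486 for MS against PD, 2, 1 and 66 in the averages at 24 h, 5d and 7d, and 21, 0 and 67 between segments at 1 h, 5d and 7d. Without 7 libraries they were 428 in MD at 1 h, 11 at 3 h, 25 at 24 h and 64 at 5d, 0 in PD at 7d, 137 for MS against PD, 3, 1 and 6 in the averages at 24 h, 5d and 7d, 56 and 0 between segments at 1 h and 5d, and 32 between the 5 times. edgeR gave 65 in MD at 1 h, 28 at 3 h, 0 at 24 h and 652 at 7d, 0 in MS at 5d, 126 in PD at 7d, 371 for MS against PD, 2, 18 and 137 in the averages at 24 h, 5d and 7d, 5, 1, 5 and 164 between segments at 1 h, 3 h, 5d and 7d, and 37 between the 5 times. A fit of each segment alone gave 1 in MS and 0 in PD at 7d, and 0 in MD at each of the 5 times. With 1 difference per mouse, 6 genes differed between the 5 times. In 1 fit over all libraries the averages gave 3 at 24 h and 26 at 7d. Of the gene list tests outside the averages, 13 passed with an estimated correlation.

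With 1 mouse left out at a time, counts at 1 h ran from 0 (without mouse 1, 2 or 4) to 1 in PD and from 1 (without mouse 1) to 457 (without mouse 2) in MD, with 167 without mouse 3. At 3 h they ran from 0 to 260 (without mouse 2; 156 without mouse 1) in PD and from 0 (without mouse 1 or 4) to 36 (without mouse 2) in MD, with 2 without mouse 3. In MD at 24 h they were 3 without mouse 2 and 0 without any of the others. At 5d they ran from 0 (without mouse 1, 2 or 3) to 1 in MS and from 9 (without mouse 5) to 1167 (without mouse 2) in MD, with 43 without mouse 4 and 596 without mouse 1. At 7d they ran from 0 to 1 (without mouse 1) in MS, from 0 (without mouse 2) to 1070 (without mouse 4) in PD, with 374 and 817 without mouse 1 and 3, and from 199 (without mouse 4) to 661 (without mouse 2) in MD, with 532 and 624 without mouse 1 and 3.

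In the averages the ranges were 1 (without mouse 1, 4 or 5) to 2 at 1 h, 0 (without mouse 1, 2 or 3) to 2 (without mouse 4) at 24 h, 0 (without mouse 1, 4 or 5) to 9 (without mouse 2) at 5d, with 3 without mouse 3, and 1 (without mouse 2) to 243 (without mouse 3) at 7d, with 10 and 5 without mouse 1 and 4. Between segments they were 0 to 37 (without mouse 2) at 1 h, with 5 without mouse 3, 0 to 2 (without mouse 2) at 3 h, 0 (without mouse 1, 4 or 5) to 31 (without mouse 2) at 5d, with 1 without mouse 3, and 23 to 228 (without mouse 4) at 7d, with 137 and 156 without mouse 1 and 3. Between the 5 times they ran from 4 (without mouse 1 or 2 of 24 h) to 26 (without mouse 2 of 1 h). For MS against MD the range was 662 (without mouse 4 of 24 h) to 1300 (without mouse 2 of 7d), with 677 without mouse 4 of 7d. For MS against PD it was 42 to 669 (without mouse 3 or 2 of 3 h), and for PD against MD 127 (without mouse 4 of 24 h) to 365 (without mouse 2 of 7d). Of the 22 mice, 15 moved the count of MS against PD by more than 1.5 times when left out, 4 that of PD against MD and 9 that between the 5 times. The counts of 0 in MS at 1, 3 and 24 h, in PD at 24 h and 5d, in the average at 3 h and between segments at 24 h stayed at 0 whichever mouse was left out, and that of 1 between 7d and 5d stayed at 1. With all mice limma had 16, 30, 40, 171, 322, 1113 and 168 genes at an unadjusted p under 0.05 where the count was 0, and edgeR called 0 in each. In MS the spread shared with the other segments makes the tests strict, so a stable count of 0 there is weak evidence of no change.

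Sost, which passed at no time, changed sign in some averages. With the covariates it was at 0.32 at 5d and -0.11 at 7d, without the 4 libraries at 0.47 at 5d, without 7 libraries at 0.47 at 5d and -0.078 at 7d, and with edgeR at 0.26 at 5d. With 1 mouse left out it ran from -0.51 to 0.46 (without mouse 2) at 1 h, from -0.043 (without mouse 2) to 0.43 at 3 h, from -0.44 to 0.20 (without mouse 4; 0.018 without mouse 5) at 5d and from -0.20 (without mouse 2; -0.024 without mouse 3) to 0.42 at 7d.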

Other observations

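The tests of other splits of the samples were chosen only after the results were seen, as were the averages over segments.

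Other gene groups moved in the averages as well. At 3 h, 30 of 34 oxidative phosphorylation genes had a negative difference, with a median of -0.30 (adjusted p = 1.48e-07 for the list, 0.716 with an estimated correlation). At 24 h, 17 of 20 interferon response genes were negative, with a median of -0.48 (adjusted p = 2.90e-04 for the list, 0.0720 with an estimated correlation). At 7d, 32 of 35 cell cycle genes were positive, with a median of 0.44 (adjusted p = 0.00182 for the list, 0.592 with an estimated correlation), and 12 of 14 B lymphocyte genes were positive, with a median of 0.57 (adjusted p = 0.0143 for the list, 0.449 with an estimated correlation). Erythroid genes were lower at 5d, with a median of -0.49 (adjusted p = 5.50e-04 for the list, 0.464 with an estimated correlation), and the list had an adjusted p of 0.292 without the 4 libraries high in Msln. By segment the erythroid list fell in the mid-diaphysis and rose in the proximal diaphysis (unadjusted p = 8.43e-09 and 0.001715 by camera).

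The limb labels were exchanged between the samples of a segment and time, in all 35 splits with 4 mice and in 100 with 5. For Fosb, the 1 gene called in the proximal diaphysis at 1 h, 3 of the 100 splits gave as many genes (highest other 1). Of these, 14 splits part the limbs of every mouse, and 1 of the 14, the real one, gave as many (highest other 0), too few splits for a share under 0.05. Chance cannot be excluded for the counts in the mid-diaphysis. At 1 h 60 of 100 splits gave at least the 41 genes called (highest other 1998), at 3 h 3 of 35 gave at least 7 (highest other 11), at 24 h 6 of 35 at least 1 (highest other 11), at 5d 18 of 100 at least 385 (highest other 1576) and at 7d 15 of 35 at least 350 (highest other 1013). The highest counts at 1 h, 24 h and 5d are several times the real ones, and what raises them was not tested. Nor can it be excluded for the proximal diaphysis at 7d, where 8 of 35 splits gave at least 205 genes (highest other 718), although among the 8 splits that part the limbs as the mice do, 1, the real one, gave as many (highest other 156). At 7d the highest counts in both diaphyseal segments were also several times the real ones, and no library high in Msln is among these samples. At 5d in the metaphyseal shell 7 of 100 splits gave at least 1 gene (highest other 1). Where the real count was 0 every split gave as many, 100 of 100 in the shell at 1 h (highest other 0) and in the proximal diaphysis at 5d (32), and 35 of 35 in the shell at 3 h (14), 24 h (0) and 7d (1) and in the proximal diaphysis at 3 h (273) and 24 h (0).

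For the averages over segments the splits were too few for a share under 0.05. With 16 splits at 1 h and 5d, 1 and 1 gave as many as the real 2 and 5 genes (highest other 1 and 0). With 8 splits at 3 h, 24 h and 7d, 8, 1 and 3 gave as many as the real 0, 1 and 16 genes (highest other 0, 0 and 180). In control limbs chance can be excluded for the metaphyseal shell against the mid-diaphysis (1 of 100 splits with at least 1031 genes, highest other 95) and against the proximal diaphysis (1 of 100 with at least 217, highest other 0). It cannot for the 2 diaphyseal segments (5 of 100 with at least 250, highest other 498). For a response that differs between segments 4 of 100 splits gave at least the 3 genes of 5d (highest other 21, several times the real count), a share under 0.05, but the count was 0 without the 4 libraries high in Msln, without mouse 1, 4 or 5, without the mouse block and in separate fits. Chance cannot be excluded at 7d (41 of 100 with at least 32, highest other 658), and with 0 genes called at 1, 3 and 24 h all 100 splits gave as many (highest other 77, 2 and 0). For the 17 genes that differed between the 5 times the share was under 0.05 (2 of 100, highest other 161, several times the real count), but the count was 6 with 1 difference per mouse, 7 without the mouse block and 4 without mouse 1 or 2 of 24 h. Chance cannot be excluded for the 1 gene between 7d and 5d (8 of 100, highest other 5).

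Gene lists were tested in the same splits, that is by permutation of the limb labels, with the unadjusted p of camera. The splits that part the limbs of every mouse numbered 8 with 4 mice and 10 or 14 of those drawn with 5, too few for a share under 0.05, so the shares below are over all splits and set aside which limbs belong to 1 mouse. That share was under 0.05 for the immediate early genes at 1 h in the metaphyseal shell (1 of 100 permutations, p = 2.47e-15, smallest other 5.37e-11), and not in the proximal diaphysis (5 of 100 permutations, p = 1.12e-06, smallest other 8.86e-09) or mid-diaphysis (22 of 100 permutations, p = 8.47e-04, smallest other 3.41e-09). For the osteoclast genes at 24 h it was under 0.05 in the metaphyseal shell (1 of 35 permutations, p = 1.02e-09, smallest other 1.98e-09) and proximal diaphysis (1 of 35 permutations, p = 1.97e-06, smallest other 3.24e-06), and not in the mid-diaphysis (4 of 35 permutations, p = 0.00130, smallest other 6.15e-06). For the secretory pathway at 24 h it was under 0.05 in the mid-diaphysis (1 of 35 permutations, p = 2.47e-08, smallest other 3.07e-07) and not in the proximal diaphysis (3 of 35 permutations, p = 0.00270, smallest other 9.24e-05). For the osteoblast and bone matrix genes at 5d it was under 0.05 in the metaphyseal shell (1 of 100 permutations, p = 4.28e-07, smallest other 1.93e-06) and proximal diaphysis (1 of 100 permutations, p = 7.59e-10, smallest other 5.68e-09), and not in the mid-diaphysis (9 of 100 permutations, p = 1.43e-09, smallest other 6.97e-13). At 7d it was under 0.05 for these genes in no segment (9, 7 and 8 of 35 permutations from the shell to the mid-diaphysis). For the chondrocyte and growth plate genes in the metaphyseal shell at 3 h it was not (5 of 35 permutations, p = 6.78e-33, smallest other 1.06e-55). Nor was it for this list in the shell at 1 h (7 of 100), 24 h (6 of 35) or 7d (5 of 35). For the skeletal muscle genes it was under 0.05 in the proximal diaphysis at 5d (3 of 100) and the shell at 7d (1 of 35). It was not in the shell (37 of 100) or mid-diaphysis (18 of 100) at 5d. The same held in the proximal diaphysis (12 of 35) and mid-diaphysis (3 of 35) at 7d and the mid-diaphysis at 24 h (7 of 35).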
